A study of Mus musculus with 80 samples.

How the data were processed

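Bulk RNA-seq of sorted mouse olfactory sensory neurons was taken from 80 deposited files, each of a library. Per the labels' protocols, tissue was dissociated with papain, cells were sorted by fluorescence, and libraries were made with a stranded total RNA kit. Cycloheximide was present during dissociation in the reporter experiments. Per the submitters' processing notes, the authors quantified reads per transcript with Salmon 0.13.1 against the mouse build GRCm38 (mm10). Each deposited table gives an estimated count of reads per transcript, which is not normalised. It also gives the TPM that the authors computed with effective lengths, per the file headers. Whether the estimates used strand is not stated in the labels.

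Estimated reads were summed per gene symbol through the gene annotation GENCODE for the same build. Of 63619 Ensembl transcripts 63514 matched, 48 gene identifiers that share a symbol were summed, and 22384 symbols resulted, of which 1174 are receptor genes. The tables also list 1761 receptor transcripts without a gene name, which held 0.0899 to 0.760% of all reads and 18.6 to 55.0% of receptor reads; they were left out because they could not be assigned to genes, so receptor values miss those reads. Entries for GFP, tdTomato and lacZ are listed for 66 libraries and not for Ctrl 1 and 2 or the developmental series. Total estimated reads per library ranged from 1.25e+07 to 4.27e+07. For a gene at 0 in a whole group, folds were computed against a floor of 3 counts per library.

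Libraries were grouped by experiment, population and genotype from the labels. Within each experiment, genes that passed edgeR's filterByExpr were scaled by TMM and tested with edgeR 4.0.16 by robust quasi-likelihood fits on rounded counts, in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in a comparison were called. Standard errors of log2 fold changes come from these fits. Gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted over all lists of a comparison. The 22 lists covered targets of the integrated stress response, ER chaperones and degradation factors, axon guidance and adhesion, activity-dependent genes, dorsal and ventral zones, precursor, immature and mature neuron markers, sustentacular, horizontal basal, Bowman's gland, microvillar, ensheathing glia, immune, erythroid, endothelial and mesenchymal, respiratory and vomeronasal markers, the dissociation response, mitochondrially encoded RNAs and receptor feedback genes. All receptor genes and receptor classes I and II were tested beside them. Correlations across genes used 1e+05 permutations. Values were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and, in R, data.table at version 1.17.8.

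The design, the comparisons, the alternatives and the rule for named genes were set before the data were examined. By that rule the text may name, per comparison, Ddit3, Atf5, Olfr17, Olfr151 and Olfr1507; up to 6 called members of each list per direction by smallest adjusted p, with uncalled members of the lists a comparison is about; the 8 called non-receptor genes with the largest change per direction among those with a mean log2 CPM of at least 4; the 6 called receptors per direction with the smallest adjusted p; and all called genes where there are fewer than 10. Genes named outside it are stated as chosen after their values were seen.

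Samples with the same number come from the same animal in the Ctrl, swap and Mor28 experiments, per the labels, so high and low, and tdTomato and GFP, are paired there. The mean correlation of deviations of same-numbered samples was 0.380 for Ctrl immature, 0.286 for Ctrl mature, 0.300 and 0.218 for swap immature and mature neurons, and 0.114, 0.204 and 0.299 for Mor28 cKO, Het and WT. Elsewhere the samples share only a number.

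The test was checked on simulated counts with known changes. For Ctrl mature neurons it recovered 53.7% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97.0% of those changed 4-fold among 16536 genes, with 7 false calls of 164. For the developmental step to mature neurons it recovered 0, 14.9 and 83.3% among 14490 genes, with 7 false calls of 72. For Mor28 cKO tdTomato against GFP neurons it recovered 32.8, 71.6 and 87.9% among 15207 genes, with 8 false calls of 136. For Mor28 tdTomato neurons of cKO against WT mice it recovered 19.4, 64.2 and 90.9% among 15229 genes, with 3 false calls of 119, and for Omp-Cre cKO against Het 80.6, 95.5 and 98.5% among 14591 genes, with 7 false calls of 190.

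Alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors, no filter on low counts, library sizes without receptor genes, a fit of only the groups compared, the replicate number as a block, the submission set as a term, each replicate left out in turn, and TPM in place of CPM for the altered genes. The libraries fall into 2 submission sets, told apart by the wording of their protocols, with 51 libraries in the first and 29 in the later set.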

Results

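RNA of sorted mouse olfactory sensory neurons was sequenced in 80 bulk libraries, made with a stranded total RNA kit for low input, in 5 experiments. A developmental series held immediate neuronal precursors (INP, n = 2), immature neurons (iOSN, n = 2) and mature neurons (mOSN, n = 2). In control mice (Ctrl) with a fluorescent reporter at Atf5 and GFP at Omp, immature and mature neurons were each sorted into high and low reporter signal (n = 6 for each of 4 groups, from 6 animals). The same 4 populations came from swap mice (n = 3 each), in which the coding sequence of the receptor M71 (Olfr151) with lacZ stands at the locus of the receptor P2 (Olfr17). In mice aged 4 weeks, neurons that express the receptor Mor28 (Olfr1507) were sorted by allele, GFP from the allele without Cre and tdTomato from the allele with Cre, in mice labelled Ddit3 cKO (n = 4), Het (n = 5) and WT (n = 3). The last experiment held tdTomato neurons of Omp-Cre mice at postnatal day 9, labelled Ddit3 cKO (n = 5), Het (n = 5) and WT (n = 4). Libraries held 1.25e+07 to 4.27e+07 estimated reads. Reads came from PCR without molecular identifiers, so the floors used for undetected genes cover counting error only, and values of single receptor genes are uncertain because similar paralogs share reads. Changes are given as log2 fold changes ± SE and group levels as mean CPM (counts scaled to a common library size) ± SD. Adjusted p-values are from edgeR unless camera, limma's gene set test, is named.

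The genes that the mouse lines alter were examined first, in the GRCm38 build. Ddit3 (ENSMUSG00000025408.15, chromosome 10, 127290774 to 127296288) encodes CHOP, a transcription factor of the unfolded protein response. Its reads did not fall in the libraries labelled cKO. In Omp-Cre neurons Ddit3 stood at 110 ± 12.7 CPM in libraries labelled cKO (93.9 to 127, n = 5), 88.4 ± 9.88 in Het (72.2 to 97.7, n = 5) and 97.2 ± 6.51 in WT (91.1 to 106, n = 4). Mor28 tdTomato neurons carried 78.2 ± 13.9 CPM in libraries labelled cKO (60.2 to 92.2, n = 4), 66.2 ± 9.05 in Het (n = 5) and 62.7 ± 12.7 in WT (48.0 to 70.3, n = 3). Counts per gene do not show a deletion that leaves a transcript, so these values check no label. The share of Ddit3 reads on the shorter of its 2 transcripts, examined after the values were seen, was 0.152 ± 0.0132 in Omp-Cre libraries labelled cKO, 0.197 ± 0.0249 in Het and 0.376 ± 0.0259 in WT. All 5 cKO libraries lay below the 5 Het and 4 WT ones, and all 5 Het libraries below the WT ones (exact two-sided permutation p = 0.0079, 0.016 after Benjamini-Hochberg adjustment over 6 comparisons, for each). In Mor28 cKO mice it was 0.116 ± 0.0893 in tdTomato and 0.364 ± 0.112 in GFP neurons. All 4 tdTomato libraries lay below the GFP ones (exact permutation p = 0.029, 0.043 adjusted). This test ignores pairing, and 4 pairs are too few for p under 0.05. WT shares were 0.274 ± 0.218 in tdTomato and 0.274 ± 0.0882 in GFP neurons. Exact permutation p against cKO was 0.26 and 0.31 (0.31 adjusted). Olfr1507 (ENSMUSG00000059887.7, chromosome 14, 52488791 to 52495749), the receptor that the Mor28 alleles tag, reached 10394 ± 332, 10725 ± 256 and 10812 ± 228 CPM in GFP neurons of cKO, Het and WT mice, against 4292 ± 560, 4498 ± 520 and 4161 ± 315 in tdTomato neurons. GFP reads stood at 7705, 7688 and 7296 CPM in GFP neurons of these genotypes and at 5.82, 10.3 and 1.34 CPM in tdTomato neurons. Reads of tdTomato stood at 891, 799 and 751 CPM in tdTomato neurons and at 11.7, 13.6 and 11.4 CPM in GFP neurons. In swap mice lacZ stood at 15.0 CPM in high and 3.25 CPM in low mature neurons, and at 6.85 and 2.11 CPM in high and low immature neurons. It was at 0 in the Ctrl libraries whose tables list it. Reads of Olfr17 remained in swap mice, at 4.75 CPM in high and 6.81 CPM in low mature neurons, against 3.79 and 6.83 CPM in Ctrl mice. Olfr151 stood at 1.50 and 0.473 CPM in high and low mature neurons of swap mice, against 0.971 and 0.394 CPM in Ctrl mice.

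The step from precursor to immature neuron was examined in the developmental series. Ddit3 stood at 49.5 ± 19.7 CPM in precursors, 180 ± 17.7 in immature and 121 ± 3.99 in mature neurons (n = 2 each). Atf5 (ENSMUSG00000038539.15, chromosome 7, 44812256 to 44816658), a transcription factor translated when the unfolded protein response is active, stood at 634 ± 262, 1093 ± 161 and 898 ± 69.1 CPM. From precursor to immature neuron Ddit3 differed by 1.87 ± 0.28 (adjusted p = 0.054) and Atf5 by 0.79 ± 0.30 (adjusted p = 0.17), so neither passed the test. The count of called genes was 6 of 14829, 1 higher and 5 lower, each with both immature samples beyond both precursor samples. The homeobox gene Meis2 fell by 3.87 ± 0.31 and the enolase gene Eno1b fell by 3.04 ± 0.23 (adjusted p = 0.047 for each). Umodl1 (-2.51 ± 0.21) and the phosphatase subunit Ppp2r2c (-1.57 ± 0.11) fell as well, and the receptor Olfr279 was at least 39.1-fold higher, against a floor of 3 counts per library.

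Gene groups showed more than single genes at this step. In the list of targets of the integrated stress response (PERK and ATF4) 0 of 30 members were called by edgeR, 6 were higher when adjusted over the list alone, and the list was higher by camera (adjusted p = 7.5e-09; adjusted p = 0.55 with an estimated correlation). The ER chaperones and degradation factors under ATF6 and XBP1 had 0 of 29 members called in either way and were higher as a list (adjusted p = 7.6e-08; adjusted p = 0.55 with an estimated correlation). Of 21 precursor markers 0 were called over all genes and 18 were lower when adjusted over the list alone (camera adjusted p = 8.5e-16; adjusted p = 0.55 with an estimated correlation). Markers of other cells moved too: sustentacular markers were lower (adjusted p = 1.2e-05; adjusted p = 0.55 with an estimated correlation), and 7 of 7 erythroid markers were higher when adjusted over the list alone (adjusted p = 7.5e-08; adjusted p = 0.55 with an estimated correlation). At an unadjusted p under 0.05 there were 4057 genes, and DESeq2 called 2376. The count rested on single libraries: it was 5803 without INP replicate 1, 1239 without INP replicate 2 and 0 without either iOSN replicate. In these fits the group with a replicate left out is a single library, and its spread is taken from the other groups. Ddit3 passed without INP replicate 1 (2.35, adjusted p = 1.3e-05) and without INP replicate 2 (1.53, adjusted p = 6.1e-04), in a range of 2.2e-08 to 0.43 over its alternatives.

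Maturation from immature to mature neuron changed 5709 of 14829 genes, 2874 higher and 2835 lower, and each called gene named for it had both mature samples beyond both immature samples. The transduction genes Adcy3, the adenylyl cyclase of olfactory cilia (4.61 ± 0.18, adjusted p = 1.1e-04), Pde1c, a cyclic nucleotide phosphodiesterase (4.02 ± 0.15) and Slc24a4, the exchanger that ends the odour response (6.91 ± 0.33) rose, as did Stoml3 (8.98 ± 0.87). S100a5, a calcium-binding protein whose RNA follows neuronal activity, rose from 2.90 ± 0.646 to 2610 ± 299 CPM (9.81 ± 0.48, adjusted p = 1.8e-04). Scgn (10.71 ± 0.44), Umodl1 (8.89 ± 0.27) and Pcp4l1 (5.30 ± 0.40) rose too. Of 27 markers of mature neurons 23 rose and 1 fell (26 and 1 when adjusted over the list alone; camera adjusted p = 2.1e-20, adjusted p = 0.59 with an estimated correlation). Of 22 markers of immature neurons 17 fell and 1 rose (18 and 1 over the list alone; adjusted p = 1e-20, adjusted p = 0.22 with an estimated correlation). Among those that fell were the growth cone genes Gng8 (-6.05 ± 0.32) and Marcks (-3.95 ± 0.16), Dpysl3 (-6.05 ± 0.35), the transcription factor Nhlh1 (-7.45 ± 0.34) and Insm1 (-5.13 ± 0.45). Cnpy1 (-7.44 ± 0.30), Vim (-6.42 ± 0.34) and the guidance inhibitor Draxin (-7.22 ± 0.52) fell too.

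Axon guidance and adhesion genes split at maturation. Of 46 tested, 11 rose and 11 fell (11 and 12 when adjusted over the list alone; camera adjusted p = 0.59). Those that rose included the ephrin receptor Epha5 (4.96 ± 0.30), the adhesion molecules Kirrel (6.86 ± 0.46) and Kirrel3 (3.37 ± 0.13), Sema7a (3.41 ± 0.28), the ephrin Efna3 (2.21 ± 0.17) and Lrrn1 (4.05 ± 0.32). Ephb2 (-5.37 ± 0.19), Nrp1 (-2.04 ± 0.23), its ligand Sema3a (-2.22 ± 0.26) and the teneurin Tenm4 (-1.57 ± 0.23, adjusted p = 0.0040) fell. Stress genes fell on balance: 12 of 30 integrated stress response targets fell and 2 rose (14 and 2 over the list alone; adjusted p = 0.0027, adjusted p = 0.78 with an estimated correlation), with Ndrg1 (-3.45 ± 0.23) and Stc2 (-4.18 ± 0.57) among them. Cth, an enzyme of cysteine synthesis, fell by 4.65 ± 0.81 (adjusted p = 0.0083), and missed the threshold without mOSN replicate 1 (adjusted p = 0.067) or 2 (adjusted p = 0.069), in a range of 7.3e-09 to 0.069. Ddit3 (-0.58 ± 0.27, adjusted p = 0.14) and Atf5 (-0.28 ± 0.30, adjusted p = 0.48) did not pass. Of 29 ER chaperones and degradation factors 10 fell, among them Edem1 (-1.71 ± 0.17) and Pdia6 (-1.22 ± 0.17), and 2 rose (camera adjusted p = 0.14).

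Other gene groups moved as well. Activity-dependent genes rose (8 of 15, with 3 lower; adjusted p = 8.5e-04, adjusted p = 0.59 with an estimated correlation). In the mature libraries 13 of 14 sustentacular markers were higher (adjusted p = 8.5e-04, adjusted p = 0.78 with an estimated correlation). So were 5 of 7 microvillar (adjusted p = 0.0037, adjusted p = 0.78 with an estimated correlation), 4 of 5 horizontal basal (adjusted p = 0.14) and 5 of 6 respiratory markers (adjusted p = 0.083). RNA of other cells as a cause was not tested. All 13 mitochondrially encoded RNAs were higher, for example mt-Nd5 (2.53 ± 0.30; list adjusted p = 3.1e-05, adjusted p = 0.78 with an estimated correlation). Of 887 receptor genes 119 were higher and 80 lower (camera adjusted p = 0.25). Leaving out any of the 4 libraries, which leaves a group of a single library, lowered the count of called genes by more than 1.5 times, to 2174 without iOSN replicate 1, 2227 without iOSN replicate 2, 2846 without mOSN replicate 1 and 2828 without mOSN replicate 2.

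High against low Atf5 reporter signal was compared within mature neurons of Ctrl mice, to ask which genes go with the level of the stress reporter. The teneurin Tenm4 (ENSMUSG00000048078.16, chromosome 7, 96171246 to 96911093), a transmembrane protein that pairs with partners on other cells, stood at 698 ± 68.4 CPM in high and 182 ± 13.3 CPM in low neurons (n = 6 each), a change of 1.94 ± 0.08 (adjusted p = 2.2e-17). Tenm2 (ENSMUSG00000049336.16, chromosome 11, 36006656 to 37235964), of the same family, stood at 1383 ± 93.6 and 434 ± 22.6 CPM (1.67 ± 0.10, adjusted p = 4.3e-13). Of 16859 genes 2104 changed, 1201 higher and 903 lower; with the animal as a block it was 3584, and 1335 without Ctrl 6. Each called gene named in this comparison had its direction in 6 of 6 animals. Of 50 guidance and adhesion genes 10 rose and 4 fell (13 and 4 when adjusted over the list alone), and the list was higher by camera (adjusted p = 0.0025; adjusted p = 0.28 with an estimated correlation). Pcdh17 (0.77 ± 0.09), Sema3a (0.82 ± 0.14), Plxnc1 (0.65 ± 0.12) and Ephb2 (0.91 ± 0.16) rose, while Epha5 (-1.12 ± 0.20), Lrrn1 (-1.10 ± 0.16) and Sema7a (-1.16 ± 0.30) fell.

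Stress genes were higher at high reporter signal in mature neurons. Of 30 integrated stress response targets 14 rose and 0 fell by edgeR (15 and 0 over the list alone; camera adjusted p = 5.6e-06, adjusted p = 0.37 with an estimated correlation). They included Ddit3 (132 ± 38.2 against 73.2 ± 22.3 CPM; 0.85 ± 0.22, adjusted p = 0.0080), the pseudokinase Trib3 (1.14 ± 0.26), Stc2 (1.68 ± 0.21), Cth (1.56 ± 0.24), Ndrg1 (1.17 ± 0.17), Aldh1l2 (0.95 ± 0.19) and the transcription factor Cebpb (0.83 ± 0.21). Atf5 RNA was higher in 6 of 6 animals (835 ± 209 against 740 ± 182 CPM). It did not pass (0.17 ± 0.17, adjusted p = 0.67, or 0.13 with the animal as a block). Of 30 ER chaperones and degradation factors 3 rose: Edem1 (1.59 ± 0.15), the sensor Ern1 (0.46 ± 0.09) and Sel1l (0.38 ± 0.05). The list did not pass (camera adjusted p = 0.30).

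High reporter signal in mature neurons also went with genes of immature neurons. Of 22 immature markers 16 rose and 0 fell (17 and 0 over the list alone; camera adjusted p = 6.9e-28, adjusted p = 8.7e-05 with an estimated correlation). Among them were Gap43 of the growth cone (280 ± 44.8 against 67.7 ± 8.94 CPM; 2.05 ± 0.14), Gng8 (2.00 ± 0.18), Stmn1 (1.53 ± 0.16), Dpysl3 (1.52 ± 0.16) and Marcks (0.98 ± 0.09). Of 27 mature markers 13 fell and 0 rose (13 and 1 over the list alone; adjusted p = 3.2e-13, adjusted p = 0.16 with an estimated correlation). They included Adcy3 (-1.17 ± 0.14), Pde1c (-1.04 ± 0.09), the chloride channel Ano2 (-0.84 ± 0.15) and Slc24a4 (-1.16 ± 0.25). Among non-receptor genes with a mean log2 CPM of at least 4 the largest rises were in Cnpy1 (3.24 ± 0.26), the polysialyltransferase St8sia2 (2.31 ± 0.18) and the kinase Stk32a (2.27 ± 0.17), and Insm1 rose by 1.72 ± 0.24. S100a5 fell from 1439 ± 294 CPM in low to 234 ± 64.9 CPM in high neurons (-2.62 ± 0.32), and Pcp4l1 (-2.47 ± 0.19), the retinoic acid hydroxylase Cyp26b1 (-2.37 ± 0.35) and Cd36 (-1.78 ± 0.35) fell as well. Activity-dependent genes were lower as a list (5 of 16 fell, 2 rose; 6 and 2 over the list alone; adjusted p = 0.0030, adjusted p = 0.57 with an estimated correlation), with Calb2 among the members that rose (1.43 ± 0.17). Of 972 non-receptor genes higher at high signal and tested in the developmental series, 703 fell and 10 rose from immature to mature neuron; of 780 lower ones, 586 rose and 19 fell there.

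As lists, other cell types and processes moved little between high and low mature neurons. Mitochondrially encoded RNAs were lower (2 of 13, such as mt-Atp6, -0.45 ± 0.08; 3 over the list alone; camera adjusted p = 0.0019, adjusted p = 0.71 with an estimated correlation). None of the remaining lists passed camera: dorsal zone (adjusted p = 0.75), ventral zone (0.38), precursor (0.94), sustentacular (0.43), horizontal basal (0.53), Bowman's gland (0.45), microvillar (0.70), ensheathing glia (0.94), immune (0.81), erythroid (0.95), endothelial and mesenchymal (0.93), respiratory (0.70), vomeronasal (0.10), dissociation response (0.48) and receptor feedback genes (0.70). Few of their members were called, for example 2 of 6 vomeronasal markers, which rose, and 0 of 14 sustentacular and 0 of 14 immune markers by edgeR. The precursor list had a median of -0.20 and a test above 0, and the erythroid list a median of 0.50 and a test below 0.

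**Figure D1:**
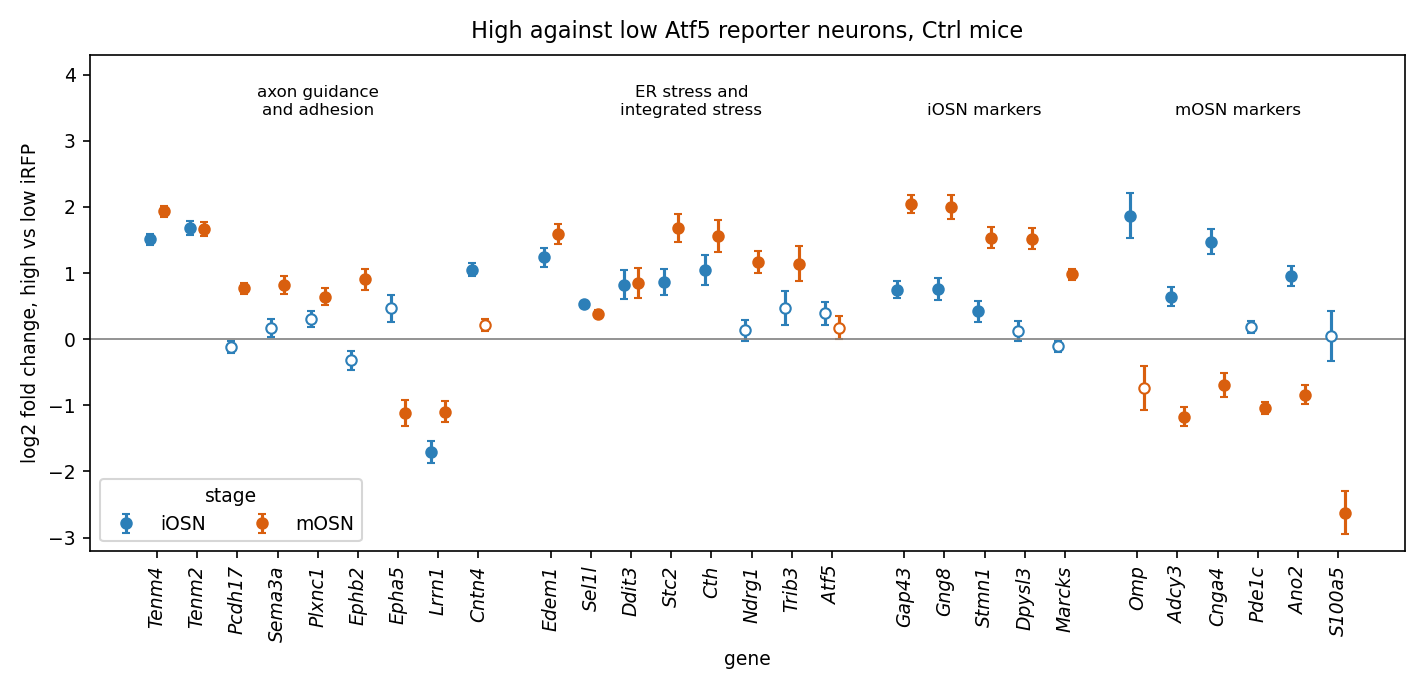
Log2 fold changes (y axis) of named genes (x axis) in high against low Atf5 reporter neurons of Ctrl mice, immature and mature neurons side by side; bars are SE from the edgeR fit, 6 animals per group. Tenm4 lies at 1.51 in immature and 1.94 in mature neurons, and S100a5 at -2.62 in mature neurons.

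Immature neurons of the same mice were compared in the same way. Tenm4 stood at 732 ± 83.0 CPM in high and 257 ± 31.4 in low neurons (1.51 ± 0.08, adjusted p = 2.3e-14), and Tenm2 at 1343 ± 69.8 and 418 ± 104 CPM (1.68 ± 0.10, adjusted p = 5.2e-13). Of 50 guidance and adhesion genes 21 rose and 14 fell (23 and 16 over the list alone); the list was higher by camera (adjusted p = 2.7e-04, adjusted p = 0.21 with an estimated correlation) with a median of 0.21 and a mean of -0.13. The protocadherin Pcdh11x (2.32 ± 0.20), Cntn4 (1.05 ± 0.10), the reelin receptor Lrp8 (1.34 ± 0.14) and Pcdh9 (0.90 ± 0.09) rose, and Lrrn1 (-1.71 ± 0.17) fell. Of 30 ER chaperones and degradation factors 12 rose and 0 fell (12 and 0 over the list alone; adjusted p = 2.1e-04, adjusted p = 0.44 with an estimated correlation), such as Edem1 (1.24 ± 0.14), Sel1l (0.53 ± 0.05) and Selenos (0.91 ± 0.11). Of 30 integrated stress response targets 13 rose and 2 fell (13 and 2 over the list alone; adjusted p = 0.013, adjusted p = 0.56 with an estimated correlation), with Ddit3 at 182 ± 40.0 against 103 ± 39.3 CPM (0.82 ± 0.22, adjusted p = 0.0046). Atf5 did not pass (0.40 ± 0.17, adjusted p = 0.081) and passed with the animal as a block (0.39, adjusted p = 2.2e-04, in a range of 2.2e-04 to 0.95 over its alternatives). In all, 5391 of 16859 genes changed, 2835 higher and 2556 lower, and each called gene named here had its direction in 6 of 6 animals. Of 27 mature markers 20 rose and 2 fell (21 and 2 over the list alone; adjusted p = 3.1e-11, adjusted p = 0.25 with an estimated correlation), for instance the G protein Gnal (1.67 ± 0.24), the channel Cnga2 (1.34 ± 0.16) and Faim2 (2.25 ± 0.27). Of 2574 non-receptor genes higher at high signal and tested in the developmental series 916 rose and 319 fell from immature to mature neuron, and of 2099 lower ones 382 rose and 501 fell.

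Markers of other cells were lower in the high immature libraries too. The low libraries of the first submission set (Ctrl 1 to 4, Swap 1 and 2) carried 868 to 4256 CPM of the collagen gene Col1a1. Those of the later set (Ctrl 5 and 6, Swap 3) carried 64.3, 26.2 and 276 CPM. In Ctrl mice 12 of 14 sustentacular markers fell (camera adjusted p = 1.1e-05, adjusted p = 0.44 with an estimated correlation). Of precursor markers 15 of 20 fell (adjusted p = 2.8e-05, adjusted p = 0.44 with an estimated correlation). So did 7 of 10 endothelial and mesenchymal (adjusted p = 0.0041, adjusted p = 0.47 with an estimated correlation) and 6 of 13 Bowman's gland markers (adjusted p = 0.018, adjusted p = 0.47 with an estimated correlation). The same held for 4 of 9 ensheathing glia (adjusted p = 0.013, adjusted p = 0.47 with an estimated correlation) and 6 of 9 ventral zone members (adjusted p = 4.1e-04, adjusted p = 0.21 with an estimated correlation). Without the iOSN libraries of Ctrl 1 to 4, a choice made after the values were seen, 551 genes were called; 4998 of the 5391 kept their sign and 528 were called in both. Tenm4 (1.55), Tenm2 (1.28), Cntn4 (0.69), Lrp8 (0.97), Lrrn1 (-1.52), Edem1 (1.10), Gnal (1.31), Faim2 (1.81), the dopamine receptor Drd2 (2.36) and the nuclear factors Nfia (-1.67) and Nfib (-0.93) passed in this fit too. Ddit3 (0.63, adjusted p = 0.44, in a range of 6.5e-07 to 0.44), the guidance receptor Dcc (-1.97, adjusted p = 0.42), Col1a1 (-1.52, adjusted p = 0.68) and the cell cycle gene Top2a (-0.51, adjusted p = 0.90) did not.

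Whether the effect of reporter level differs between the stages was tested as the mature minus the immature log2 fold change. The difference passed for 3289 genes, 1549 above 0 and 1740 below 0 (5278 with the animal as a block). Of 22 immature markers 14 were above 0 and 1 below 0 (14 and 1 over the list alone; camera adjusted p = 3.3e-09, adjusted p = 0.036 with an estimated correlation). Examples were Gap43 (1.30 ± 0.18), Dpysl3 (1.40 ± 0.22), Marcks (1.09 ± 0.12) and Nhlh1 (1.36 ± 0.26). Of 27 mature markers 24 were below 0 and 1 above 0 (24 and 1 over the list alone; adjusted p = 2.8e-27, adjusted p = 0.032 with an estimated correlation), such as Omp (-2.61 ± 0.48), Adcy3 (-1.82 ± 0.20), Cnga4 (-2.17 ± 0.26) and Faim2 (-2.73 ± 0.37). Guidance genes went both ways, 11 above 0 and 14 below 0 of 50 (13 and 18 over the list alone; adjusted p = 0.28, with a median of -0.07 and a mean of 0.18). Pcdh17 (0.88 ± 0.13) and Ephb2 (1.22 ± 0.21) lay above 0, and Cntn4 (-0.83 ± 0.14), Plxna4 (-1.52 ± 0.24), Lrp8 (-1.03 ± 0.19) and the cadherin Cdh23 (-3.77 ± 0.32) below 0. Selenos (-1.13 ± 0.16) and Atf6 (-0.57 ± 0.08) were among 7 of 30 ER chaperones and degradation factors below 0 (adjusted p = 0.031, adjusted p = 0.68 with an estimated correlation). Ddit3 (0.03 ± 0.31) and Atf5 (-0.22 ± 0.25) showed no difference that passed (adjusted p = 0.97 and 0.59). The difference for Tenm4 was 0.43 ± 0.11 (adjusted p = 0.0068), and 0.38 (adjusted p = 0.093, in a range of 2.9e-06 to 0.093) without the iOSN libraries of Ctrl 1 to 4. Precursor (7 of 20 above 0; adjusted p = 2.3e-04, adjusted p = 0.66 with an estimated correlation) and endothelial and mesenchymal markers (6 of 10; adjusted p = 0.0088, adjusted p = 0.66 with an estimated correlation) moved with it. Without those libraries 775 genes passed, 3229 of the 3289 kept their sign and 736 of them passed.

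Receptor genes were compared between reporter levels because each neuron expresses a single receptor. In mature neurons 197 of 1042 receptor genes were higher and 114 lower at high signal. Olfr1537 stood at 50.8 ± 16.5 CPM in high and 1.29 ± 0.868 in low neurons (5.29 ± 0.42, adjusted p = 1.0e-10), and Olfr859 at 44.9 ± 14.0 and 0.648 ± 0.602 CPM (6.01 ± 0.49). Olfr857 rose by 8.09 ± 0.79. In the other direction Olfr1226 stood at 2.21 ± 3.46 and 93.1 ± 11.2 CPM (-5.29 ± 0.65, adjusted p = 5.0e-07), Olfr2 at 3.19 ± 1.63 and 59.5 ± 14.3 CPM (-4.21 ± 0.44), and Olfr569 (-9.03 ± 1.19) and Olfr166 (-2.29 ± 0.29) fell. Of 117 class I receptors, the family related to those of fish, 43 fell and 3 rose (62 and 4 over the list alone; camera adjusted p = 1.7e-14, adjusted p = 0.0022 with an estimated correlation). Of 925 class II receptors 194 rose and 71 fell (233 and 96 over the list alone; adjusted p = 0.0051, adjusted p = 0.57 with an estimated correlation). All receptors together did not pass (adjusted p = 0.28). Among the trace amine receptors Taar9 fell by 3.72 ± 0.82 and Taar6 rose by 2.38 ± 0.36. Olfr1507 rose (1.39 ± 0.37, adjusted p = 0.011), but not without Ctrl 2 (1.10, adjusted p = 0.10, in a range of 0.0035 to 0.10). Olfr151 (1.28 ± 0.87, adjusted p = 0.44) and Olfr17 (-0.85 ± 0.61, adjusted p = 0.48) did not pass.

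In immature neurons 251 receptor genes were higher and 79 lower. Olfr1537 (3.89 ± 0.39) and Olfr859 (3.65 ± 0.42) rose, and Olfr2 (-2.97 ± 0.45), Olfr166 (-1.89 ± 0.30) and Olfr455 (-5.24 ± 0.97) fell. Class I receptors were lower there (16 of 117 fell, 7 over the list alone; camera adjusted p = 0.0020, adjusted p = 0.44 with an estimated correlation). Class II receptors were higher (251 of 925 rose and 63 fell, 258 and 66 over the list alone; adjusted p = 0.0063, adjusted p = 0.47 with an estimated correlation and 0.098 with the animal as a block). Across the 1042 receptor genes, which are not independent replicates, fold changes in immature and mature neurons were correlated (r = 0.587, rho = 0.677; permutation p = 1e-05 for each, the smallest that the permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over 3 relations). Of 181 receptors called at both stages 179 had the same direction. Olfr1507 differed between the stages (2.33 ± 0.54, adjusted p = 0.0025), as did Olfr857 (5.29 ± 0.96) and Olfr418 (-2.81 ± 0.55).

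**Figure D2:**
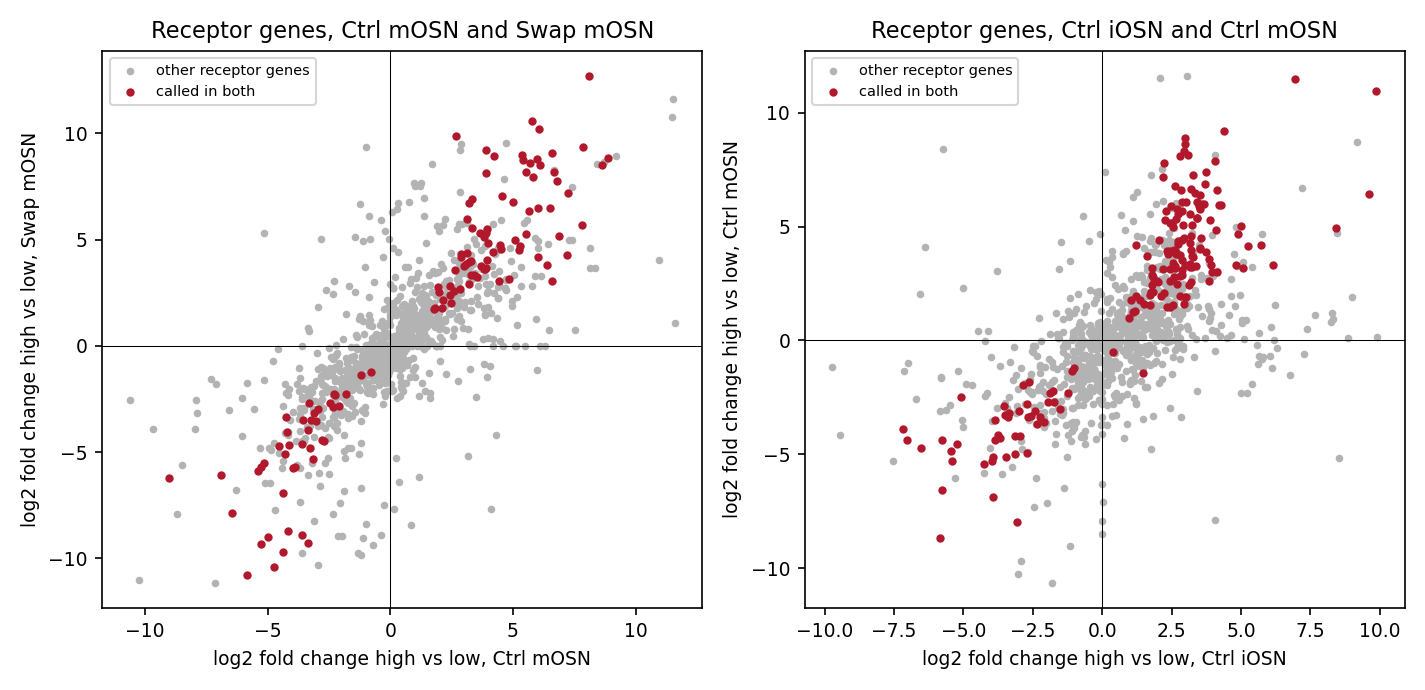
Log2 fold changes of 1042 receptor genes in high against low reporter neurons; each point is a receptor gene, and the axes are immature against mature neurons of Ctrl mice and mature neurons of Ctrl against swap mice. The points follow a rising trend, with r of 0.587 and 0.735.

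Swap mice asked whether the receptor sequence at a locus goes with reporter level. In their mature neurons Tenm4 stood at 740 ± 44.3 CPM in high and 177 ± 16.1 in low neurons (2.06 ± 0.12, adjusted p = 1.1e-13, n = 3). Tenm2 rose by 1.73 ± 0.15, Gap43 by 2.10 ± 0.19, Cnpy1 by 3.16 ± 0.36, Pcdh17 by 0.93 ± 0.13 and Plxnc1 by 1.10 ± 0.18. S100a5 (-2.61 ± 0.46), Pcp4l1 (-2.37 ± 0.27), Cyp26b1 (-2.92 ± 0.50) and Adcy3 (-1.16 ± 0.20) fell, and Edem1 (1.64 ± 0.20), Stc2 (2.06 ± 0.30) and Cth (1.77 ± 0.34) rose. Each had its direction in 3 of 3 animals. Ddit3 did not pass (0.94 ± 0.31, adjusted p = 0.082) and passed with the animal as a block (adjusted p = 1.3e-04, in a range of 1.3e-04 to 0.49). The count was 783 genes, 497 higher and 286 lower, 1838 with the animal as a block, and 395, 331 and 271 without Swap 1, 2 and 3. Immature markers rose (13 of 22, 16 over the list alone; camera adjusted p = 2.0e-25, adjusted p = 1.2e-04 with an estimated correlation). Mature markers fell (6 of 27, 13 with 1 higher over the list alone; adjusted p = 3.3e-11, adjusted p = 0.19 with an estimated correlation). Class I receptors fell (22 of 117, 44 over the list alone; adjusted p = 6.3e-20, adjusted p = 3.6e-04 with an estimated correlation). Sustentacular markers had 0 calls by edgeR and were higher as a list (adjusted p = 0.019, adjusted p = 0.90 with an estimated correlation). Olfr857 was at least 363-fold higher in high neurons, Olfr1537 rose by 4.71 ± 0.56, and Olfr1226 (-5.70 ± 0.93) and Olfr2 (-4.06 ± 0.61) fell.

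Ctrl and swap mice share no library in these comparisons. Receptor fold changes of their mature neurons were correlated across genes (r = 0.735, rho = 0.788; permutation p = 1e-05, 1e-05 adjusted), and 120 of 120 receptors called in both had the same direction. In immature neurons r was 0.530 and rho 0.650 (permutation p = 1e-05, 1e-05 adjusted), with 126 of 126. Of all genes 482 were higher in both mature comparisons (35.4 with independent lists), 277 lower (15.3) and 0 opposite by edgeR. In immature swap neurons 2711 genes changed (4885 with the animal as a block; 661 and 631 without Swap 1 and 2). Among them were Tenm4 (1.78 ± 0.12), Tenm2 (1.75 ± 0.15), Pcdh11x (1.86 ± 0.27), Cntn4 (0.99 ± 0.14), Edem1 (1.22 ± 0.20) and Cdh23 (2.57 ± 0.34), each in 3 of 3 animals. Ddit3 rose there (0.91 ± 0.31, adjusted p = 0.044) but not without any of the 3 animals (adjusted p = 0.19, 0.29 and 0.079 without Swap 1, 2 and 3, in a range of 1.1e-04 to 0.29). Tests of swap minus Ctrl called 0 genes by edgeR in mature and 0 in immature neurons, with 166 and 594 genes at an unadjusted p under 0.05 and 9 and 28 genes by DESeq2. The swapped allele itself was followed by its lacZ reads, which were 2.83-, 48.7- and 10.4-fold higher in high than low mature neurons of the 3 animals and 3.18-, 4.69- and 2.12-fold higher in immature neurons. By edgeR the change of lacZ was 2.20 ± 1.01 (adjusted p = 0.35) in mature and 1.70 ± 1.00 (adjusted p = 0.28) in immature neurons and did not pass, a test added after the values were seen. With Olfr17 reads in Ctrl and lacZ reads in swap mice taken as reads of the P2 locus, likewise after the values were seen, the high against low change differed between swap and Ctrl mice by 3.05 ± 1.05 in mature (unadjusted p = 0.0065, adjusted p = 1.0) and 1.62 ± 1.04 in immature neurons (adjusted p = 1.0), and neither passed. This measure of the locus leaves out the Olfr17 reads that swap mice still had, so it compares unlike quantities. Olfr151 (1.65 ± 1.20, adjusted p = 0.65) and Olfr17 (-0.52 ± 0.86, adjusted p = 0.93) did not pass in mature swap neurons.

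Neurons of the Mor28 Cre allele (tdTomato) were compared with those of the other (GFP) in each genotype, in WT without a floxed gene. Olfr1507 fell in tdTomato neurons of cKO (-1.28 ± 0.08, adjusted p = 2.2e-12), Het (-1.25 ± 0.07) and WT mice (-1.38 ± 0.09). Its neighbour Olfr1508 (ENSMUSG00000057564.6, chromosome 14, 52458829 to 52467495) rose by 3.10 ± 0.32, 3.23 ± 0.29 and 3.41 ± 0.37, and Olfr1280 by 10.39 ± 0.65, 8.04 ± 0.49 and 8.51 ± 0.65; Olfr743 was at least 195-fold higher in cKO mice. Class II receptors were higher in all 3 genotypes (28, 35 and 15 of 252 rose and 2 fell in each; 49, 68 and 37 rose over the list alone; camera adjusted p = 9.4e-05, 2.3e-05 and 6.2e-06 with an estimated correlation). Allele and receptor are thus not told apart. Pcp4l1 rose by 4.61 ± 0.47, 4.52 ± 0.42 and 4.45 ± 0.54, and the protocadherin Pcdh9 by 2.46 ± 0.32, 2.19 ± 0.28 and 2.55 ± 0.37. S100a5 rose from 8.98 ± 1.71 to 332 ± 66.9 CPM in cKO mice (5.21 ± 0.70) and by 4.17 ± 0.59 in Het mice. Each called gene named for these comparisons had its direction in 4 of 4, 5 of 5 and 3 of 3 animals. The counts were 199 (76 higher, 123 lower), 255 (131, 124) and 59 (36, 23) of 15614 genes, and 634, 812 and 263 with the animal as a block. In all 3 genotypes 29 genes were higher and 18 lower, where independent lists would share 0.0015 and 0.0014.

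Genes lower in tdTomato neurons included Ptprz1, a receptor phosphatase (-1.90 ± 0.18 in cKO, -1.34 ± 0.16 in Het, -1.25 ± 0.21 in WT), and Cpn1, a carboxypeptidase subunit (ENSMUSG00000025196.4, chromosome 19, 43956307 to 43986556), which fell by 2.72 ± 0.16 in cKO, 1.22 ± 0.13 in Het and 0.78 ± 0.17 in WT mice. In WT mice Ptprz1 did not pass without WT 2 (adjusted p = 0.11, in a range of 2.0e-07 to 0.11), nor Cpn1 without WT 1 or 2 (adjusted p = 0.36 and 0.73, in a range of 7.0e-04 to 0.73). In cKO mice the interferon-induced Ifit1 (-2.45 ± 0.38) and Ifit2 (-1.87 ± 0.22), the guanylate cyclase subunit Gucy1b2 (-3.13 ± 0.39), Rin1 (-2.37 ± 0.27), Lsamp (-2.45 ± 0.30), Cebpb (-1.04 ± 0.20) and Sel1l (-0.60 ± 0.09) fell. In Het mice Gucy1b2 (-1.62 ± 0.33) and Rin1 (-1.58 ± 0.23) fell, and so did Ifit1 (-1.25 ± 0.33, adjusted p = 0.049), but not without Het 1, 2, 3 or 5 (adjusted p = 0.096, 0.22, 0.12 and 0.16, in a range of 5.6e-06 to 0.22). In WT mice Ptn (-0.86 ± 0.14), Adcy5 (-1.25 ± 0.19) and Setd5 (-0.74 ± 0.10) fell. Of 48 guidance genes 3 rose and 9 fell in cKO (6 and 11 over the list alone; camera adjusted p = 0.092, 0.0093 with the animal as a block), with Unc5b (-0.86 ± 0.10) and Efna5 (-0.74 ± 0.10) among those that fell. In Het mice 4 rose and 7 fell (10 and 15 over the list alone; adjusted p = 0.74), and 3 rose and 0 fell in WT by edgeR (6 and 7 over the list alone; adjusted p = 0.60). In cKO the list had a median of -0.03 and a mean of 0.28 with a test below 0, in Het a median of 0.10 and a mean of 0.58 with a test below 0. In WT it had a median of -0.10 and a mean of 0.23 with a test above 0. Nrp2, a semaphorin receptor, fell by 0.55 ± 0.13 in cKO (adjusted p = 0.023), but not without any of the 4 animals (adjusted p = 0.12, 0.12, 0.14 and 0.12 without cKO 1 to 4, in a range of 2.3e-09 to 0.14). Activity-dependent genes were higher by camera (adjusted p = 0.0019, 9.6e-04 and 0.0047 in cKO, Het and WT; adjusted p = 0.40, 0.51 and 0.51 with an estimated correlation). Ddit3 (0.20 ± 0.19, adjusted p = 0.82) did not pass in cKO, nor did Atf5 (-0.36 ± 0.10, adjusted p = 0.092), which passed with the animal as a block (adjusted p = 5.4e-05, in a range of 5.4e-05 to 0.34). Counts moved by more than 1.5 times without cKO 1 (90) or cKO 3 (103), without Het 2 (165), and without WT 1, 2 or 3 (34, 28 and 24).

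The difference between Mor28 libraries labelled cKO and WT in the tdTomato against GFP change was tested next. It passed for 2 of 15614 genes: Cpn1 (-1.94 ± 0.23, adjusted p = 2.6e-05) and Ifit2 (-1.81 ± 0.33, adjusted p = 0.047; ENSMUSG00000045932.12, chromosome 19, 34550694 to 34576419). Cpn1 stood at 14.2 ± 3.01 CPM in tdTomato neurons of libraries labelled cKO, against 92.7 ± 3.54 in their GFP neurons, 65.5 ± 9.62 in tdTomato and 113 ± 9.70 in GFP neurons of WT mice. Ifit2 kept its call without cKO 4 and lost it without any other of the 7 animals (adjusted p = 0.55, 0.50 and 0.12 without cKO 1, 2 and 3, and 0.23, 0.27 and 0.67 without WT 1, 2 and 3, in a range of 1.4e-04 to 0.67). The count was 12 with the animal as a block, 18 by DESeq2, and 404 at an unadjusted p under 0.05. None of the gene lists had a called member by edgeR; camera found mitochondrially encoded RNAs lower (adjusted p = 2.3e-04, adjusted p = 0.85 with an estimated correlation).

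Between animals, tdTomato neurons labelled cKO differed from WT ones in 21 genes, 6 higher and 15 lower. Cpn1 fell by 2.22 ± 0.16 (adjusted p = 3.7e-10), Gucy1b2 by 2.69 ± 0.40 (adjusted p = 0.0013), and Ifit1 by 2.47 ± 0.40 (adjusted p = 0.0033). Ifit2 fell by 2.06 ± 0.23 (adjusted p = 4.1e-06), the Ras effector Rin1 by 1.73 ± 0.28 (adjusted p = 0.0013) and Stbd1, a glycogen-binding protein, by 1.19 ± 0.19 (adjusted p = 0.0022). Kif5a, a kinesin heavy chain (1.05 ± 0.11, adjusted p = 8.4e-07), the dynactin subunit Dctn2 (0.89 ± 0.11), Pip4k2c (1.15 ± 0.12) and Dtx3 (1.23 ± 0.15) rose, as did Adgb (0.65 ± 0.12, adjusted p = 0.0068) and Plch2 (0.66 ± 0.13, adjusted p = 0.024). In each case 4 of 4 cKO samples lay beyond all 3 WT samples. Adgb did not pass without cKO 2, WT 2 or WT 3 (adjusted p = 0.066, 0.20 and 0.12, in a range of 2.1e-04 to 0.21), and Plch2 did not without cKO 1, cKO 3 or any WT animal (adjusted p = 0.12 and 0.16, then 0.22, 0.15 and 0.13 without WT 1 to 3, in a range of 0.0016 to 0.22). Plxnd1, a semaphorin receptor, fell by 1.14 ± 0.21 (adjusted p = 0.0065) but not without WT 2 (adjusted p = 0.098, in a range of 3.0e-04 to 0.12). Erlin1 fell by 1.11 ± 0.18 (adjusted p = 0.0020) but not without WT 3 (adjusted p = 0.072, in a range of 1.8e-05 to 0.11). Of 48 guidance genes 1 fell (3 over the list alone; camera adjusted p = 0.0040, adjusted p = 0.43 with an estimated correlation). Of 30 integrated stress response targets 0 were called by edgeR, 3 were higher over the list alone and the list was higher (adjusted p = 4.3e-05, adjusted p = 0.42 with an estimated correlation). Sustentacular (adjusted p = 0.0028), immune (0.0038), precursor (0.0036) and mitochondrially encoded lists (6.2e-05) were lower with no estimated-correlation p under 0.42. The count was 635 at an unadjusted p under 0.05, 67 by DESeq2 and 13 without WT 2.

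In Omp-Cre mice at postnatal day 9 both submission sets hold cKO and Het libraries, so these were compared first. The transcription factor Mitf (ENSMUSG00000035158.15, chromosome 6, 97807052 to 98021349) stood at 9.19 ± 0.393 CPM in libraries labelled cKO and 21.1 ± 1.45 in Het (-1.20 ± 0.06, adjusted p = 3.4e-08, n = 5 each). Tenm4 stood at 286 ± 22.5 and 390 ± 24.9 CPM (-0.45 ± 0.07, adjusted p = 0.0081), and Tenm2 at 679 ± 44.5 and 860 ± 51.4 CPM (-0.34 ± 0.05, adjusted p = 0.0070). Of 14805 genes 36 changed, 10 higher and 26 lower, and each called gene named here had 5 of 5 cKO samples beyond all 5 Het samples. Map3k20 (-0.93 ± 0.11), Plxnd1 (-0.72 ± 0.10), Arhgef2 (-0.60 ± 0.05), Ifit2 (-0.59 ± 0.06), Stbd1 (-0.52 ± 0.06) and Cebpb (-0.44 ± 0.06) fell, as did Fam129a (-0.92 ± 0.12) and Cebpa (-0.65 ± 0.09). Kif5a (0.42 ± 0.04), Dctn2 (0.42 ± 0.04), Pip4k2c (0.53 ± 0.07), Mef2b (0.52 ± 0.06) and the ubiquitin ligase Rnf213 (0.45 ± 0.04) rose. Of 45 guidance genes 1 rose and 3 fell (1 and 11 over the list alone; camera adjusted p = 1.1e-07, adjusted p = 0.28 with an estimated correlation). Nrp2 fell by 0.45 ± 0.07 (adjusted p = 0.014), but not without cKO 2 (adjusted p = 0.063) or cKO 4 (adjusted p = 0.060), in a range of 1.9e-06 to 0.13. Of 30 integrated stress response targets 1 fell and 0 rose by edgeR (5 and 11 over the list alone), with the list higher (adjusted p = 0.0025, adjusted p = 0.37 with an estimated correlation). Ddit3 (0.31 ± 0.09, adjusted p = 0.21) and Atf5 (-0.24 ± 0.07, adjusted p = 0.27) did not pass.

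Other cell types moved in this comparison: sustentacular (camera adjusted p = 6.5e-06), immune (adjusted p = 5.9e-04), endothelial and mesenchymal (adjusted p = 0.0019) and precursor lists (adjusted p = 8.6e-05) were lower in cKO, each with adjusted p = 0.39 with an estimated correlation and 0 members called by edgeR. The count was 23 within the first submission set (4 cKO and 3 Het libraries), 106 without cKO 1, 178 by DESeq2 and 1774 at an unadjusted p under 0.05; Fam129a and Cebpa did not pass within the first set.

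Against WT, libraries labelled cKO differed in 1423 of 14805 genes, 921 higher and 502 lower. All WT libraries and 1 of the 5 cKO libraries belong to the later submission set, and within that set 24 genes were called. Mitf fell by 1.55 ± 0.06 (adjusted p = 1.5e-09), Plxnd1 by 1.16 ± 0.11, Fam129a by 1.18 ± 0.12, Ifit1 by 1.03 ± 0.13, Map3k20 by 1.03 ± 0.12 and Erlin1 by 1.00 ± 0.14, in each case with 5 of 5 cKO samples below all 4 WT samples. Of 45 guidance genes 2 rose and 13 fell (7 and 14 over the list alone; camera adjusted p = 0.013, adjusted p = 0.56 with an estimated correlation). Nrp2 (-0.53 ± 0.08), Tenm4 (-0.43 ± 0.07, adjusted p = 0.0040), Tenm2 (-0.35 ± 0.06), Pcdh17 (-0.35 ± 0.06) and Unc5b (-0.36 ± 0.06) fell, and Pcdh19 (0.53 ± 0.05) rose. Integrated stress response targets split, 8 higher and 5 lower of 30 (9 and 5 over the list alone; adjusted p = 0.38). Trib3 (-1.02 ± 0.20), Cebpb (-0.52 ± 0.06) and Ndrg1 (-0.67 ± 0.11) fell, and Cth (0.90 ± 0.18), the amino acid transporter Slc7a5 (0.42 ± 0.06), Aldh1l2 (0.54 ± 0.11) and Atf4 (0.19 ± 0.04) rose. Atf5 fell by 0.30 ± 0.08 (adjusted p = 0.024; 4 of 5 cKO samples below all WT samples), but not without cKO 3 or 4 (adjusted p = 0.061 and 0.054) or WT 1, 2 or 3 (adjusted p = 0.091, 0.061 and 0.065), in a range of 0.0021 to 0.16. Of 29 ER chaperones and degradation factors 5 rose and 2 fell (adjusted p = 0.25), with Dnajb9 (0.32 ± 0.06) higher and Sel1l (-0.31 ± 0.05) lower. Mature markers rose (7 of 27, 12 with 1 lower over the list alone; adjusted p = 3.1e-06, adjusted p = 0.56 with an estimated correlation). Mitochondrially encoded RNAs were higher beside these groups (12 of 13, mt-Co1 by 0.41 ± 0.06; adjusted p = 6.9e-20, adjusted p = 0.13 with an estimated correlation). Sustentacular markers were lower (0 called by edgeR; adjusted p = 4.0e-04, adjusted p = 0.60 with an estimated correlation). The lowest counts came without WT 1 (681), WT 2 (746), cKO 4 (783), cKO 3 (796) or WT 3 (820).

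Het against WT neurons gave 9 called genes, 5 higher and 4 lower, each with 5 of 5 Het samples beyond all 4 WT samples. Kif5a (0.39 ± 0.04, adjusted p = 6.2e-04), Dctn2 (0.40 ± 0.05), Pip4k2c (0.69 ± 0.07) and the receptor Olfr482 (at least 18.2-fold) were higher and passed in every fit that left out a single library. The calls of mt-Co1 (0.39 ± 0.06), Mitf (-0.35 ± 0.06), Arhgef2 (-0.33 ± 0.05), Carmil3 (-0.42 ± 0.07) and Ccdc136 (-0.38 ± 0.06) were each lost in several such fits. In all, 4 genes passed without any of Het 1, 2 or 3 or WT 1, 2 or 3, against 216 without Het 4 and 53 without WT 4. All 13 mitochondrially encoded RNAs were higher when adjusted over the list alone (camera adjusted p = 6.1e-29, adjusted p = 0.037 with an estimated correlation). Within the later submission set 3 genes were called; DESeq2 called 421 genes and 1931 had an unadjusted p under 0.05. Ddit3 did not pass (-0.14 ± 0.09, adjusted p = 0.57).

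**Figure D3:**
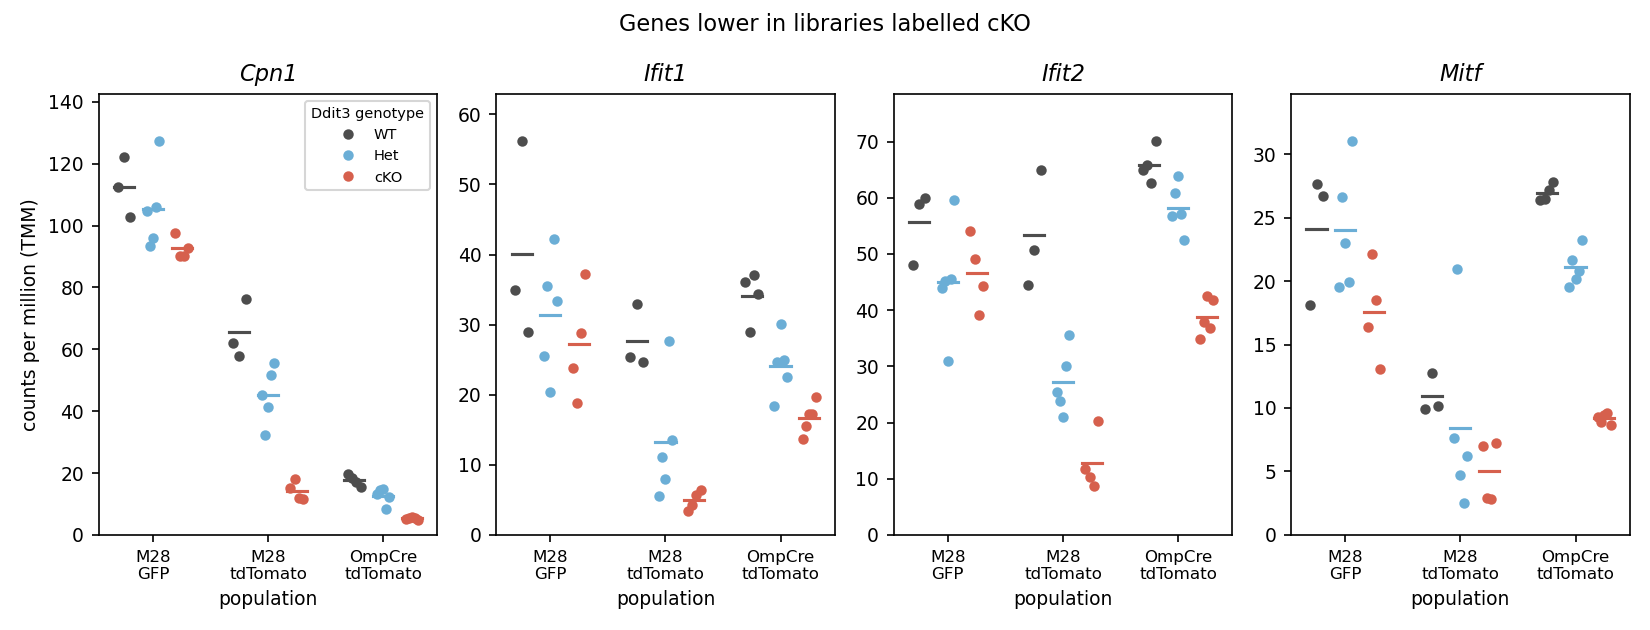
CPM (y axis) of genes named for the Ddit3 lines, by population (x axis) and Ddit3 genotype; each point is a library and the bar is the group mean. Cpn1 lies at a mean of 14.2 in Mor28 tdTomato neurons labelled cKO and 65.5 in WT, and Mitf at 9.19 and 27.0 in Omp-Cre neurons.

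Of the 6 genes that rose in tdTomato neurons of libraries labelled cKO 4 lie near Ddit3. Kif5a (ENSMUSG00000074657.5, 127225696 to 127263348), Dctn2 (ENSMUSG00000025410.10, 127266368 to 127281950), Pip4k2c (ENSMUSG00000025417.8, 127197067 to 127211585) and Dtx3 (ENSMUSG00000040415.15, 127190378 to 127195728) lie on chromosome 10 at 8.8 to 95 kb from Ddit3. They were therefore compared, after their values were seen, in GFP neurons, which express the allele without Cre. There, 4 of 15614 genes were called between cKO and WT mice, and these were the 4: Kif5a (0.95), Dctn2 (0.99), Pip4k2c (0.84) and Dtx3 (1.07). Kif5a stood at 547, 804 and 1058 CPM in GFP neurons of WT, Het and cKO mice, at 556, 830 and 1151 CPM in tdTomato neurons, and at 879, 1154 and 1540 CPM in Omp-Cre neurons. Het against WT GFP neurons gave 0 calls by edgeR with 621 genes at an unadjusted p under 0.05.

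**Figure D4:**
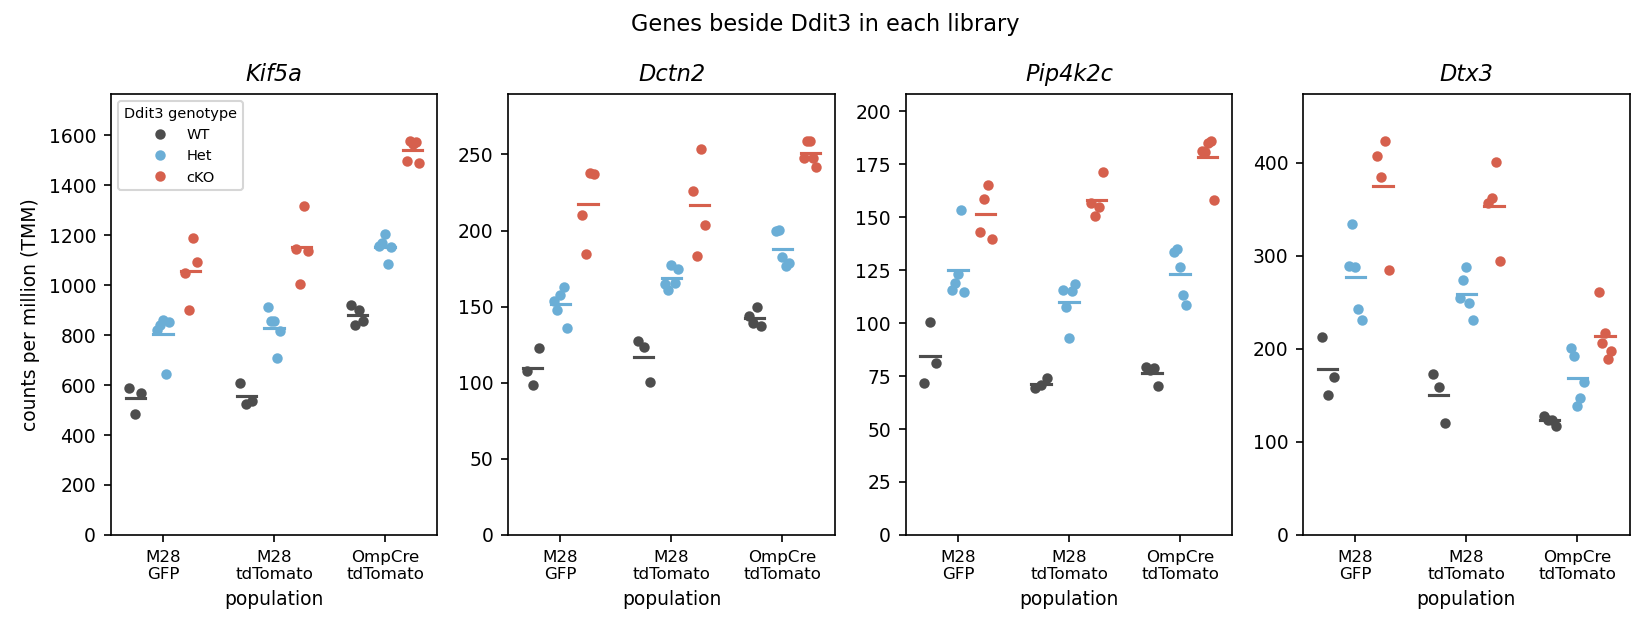
CPM (y axis) of the 4 genes next to Ddit3 on chromosome 10, by population (x axis) and Ddit3 genotype; each point is a library and the bar is the group mean. Kif5a rises from 547 in WT to 804 in Het and 1058 in cKO among GFP neurons, which express the allele without Cre.

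Genes that go with reporter level were then followed in the Ddit3 lines, which come from other animals. Of the 1004 non-receptor genes higher in high Ctrl mature neurons, 972 were tested in Omp-Cre mice, where 21 were higher and 135 lower in cKO than WT, and the set was lower (camera adjusted p = 2.6e-09, adjusted p = 0.23 with an estimated correlation). Of the 789 lower ones 779 were tested, 133 were higher and 15 lower, and the set was higher (adjusted p = 1.0e-07, adjusted p = 0.27 with an estimated correlation). The comparison with Het mice, added after the values were seen, gave the same directions (adjusted p = 2.6e-09 and 1.1e-07, adjusted p = 0.23 and 0.27 with an estimated correlation). In Mor28 tdTomato neurons the directions were the opposite: the first set was higher (adjusted p = 0.0026, adjusted p = 0.43 with an estimated correlation) and the second lower (adjusted p = 5.1e-04, adjusted p = 0.23 with an estimated correlation) in cKO than WT. The difference between genotypes in the tdTomato against GFP change gave adjusted p = 0.89 and 0.024 (adjusted p = 0.97 and 0.27 with an estimated correlation). With sets taken from immature neurons the directions in Omp-Cre cKO against WT were reversed (adjusted p = 1.5e-05 for the first set and 1.9e-08 for the second, adjusted p = 0.23 and 0.27 with an estimated correlation). Of 21 genes called between cKO and WT tdTomato neurons of Mor28 mice, 20 had the same direction between cKO and Het neurons of Omp-Cre mice. Without the 4 neighbours of Ddit3 it was 16 of 17 (binomial p = 2.7e-04, across genes, which are not independent). Those called in both were Cpn1, Plxnd1, Rin1, Stbd1, Frem2, Ifit2 and 3 neighbours, of which Cpn1, Frem2 and Rin1 were chosen after their values were seen.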

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

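The tests of maturity and of RNA of other cells, and the fits without the iOSN libraries of Ctrl 1 to 4, were chosen only after the result was seen. Samples far from the others of their group were looked for in the altered genes and in the receptor reads without a gene name: 9 of 91 groups of 4 to 10 samples had such a sample by Dixon's test, and chance gives about 1 in 20 groups, or 4.55. Olfr17 stood at 13.5 CPM in Omp-Cre cKO replicate 3, against 7.69 to 9.36 in the others. Olfr151 stood at 0.0588 CPM in Omp-Cre WT replicate 4 and at 0 in the others. Olfr1507 stood at 10886 CPM in Mor28 cKO GFP replicate 4, against 10178 to 10299, and at 57.4 CPM in Ctrl low mature replicate 1, against 21.4 to 26.7. GFP reads stood at 0.243 CPM in Omp-Cre Het replicate 1 (0 in the others), and tdTomato reads at 27.3 CPM in Mor28 Het GFP replicate 2, against 8.15 to 13.4. Reads of lacZ stood at 0.770 CPM in Mor28 cKO tdTomato replicate 4 and at 0.0712 CPM in Mor28 Het tdTomato replicate 3, with 0 in the others of each group. Receptor transcripts without a gene name held 46.6% of receptor reads in Ctrl low mature replicate 6, against 48.2 to 48.9%.

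Signals appeared in data that the comparisons did not use. The Mor28 line carries no lacZ, yet 18 lacZ reads were assigned in cKO tdTomato replicate 4. Receptor transcripts without a gene name held up to 55.0% of receptor reads, in mature replicate 2 of the developmental series.

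Effects that differed between groups were those of reporter level between mature and immature Ctrl neurons, for 3289 genes, and those of tdTomato against GFP between Mor28 cKO and WT mice, for 2 genes, Cpn1 and Ifit2, of which Ifit2 lost its call without any of 6 of the 7 animals.

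For the difference between stages, RNA of other cells in the low immature libraries of Ctrl 1 to 4 was weighed first. Of 1591 genes called for this difference in Ctrl 1 to 4 alone, 1523 were tested in Ctrl 5 and 6, with no library shared. There the difference had a median of 0.711 of its size (quartiles 0.497 and 0.930), with the same sign in 97.3%. Over all 14649 genes the values were 0.644 (quartiles -0.0148 and 1.27) and 74.7%. Without the immature libraries of Ctrl 1 to 4, 6 of 6 endothelial and mesenchymal markers called for the difference kept their sign too. None passed (Col1a1 went from 5.09 ± 1.26 to 3.16 ± 1.32), but of all 3289 genes only 736 passed in this smaller fit. These tests cannot decide on that RNA, and the split also parts the submission sets. That the high and low gates hold neurons of different maturity stays open: across non-receptor genes, which are not independent, the difference was correlated with the change from immature to mature neurons of the developmental series (r = -0.29, rho = -0.439), but a response to stress that alters maturation would give such a relation as well. GFP reads, from the reporter at Omp, stood at 523 ± 239 CPM in high and 1008 ± 367 CPM in low mature Ctrl neurons. In immature neurons they stood at 64.6 ± 38.2 and 17.6 ± 6.46 CPM (n = 4 each). The high against low change itself was correlated with that developmental change at r = -0.463 in mature and 0.0429 in immature neurons. Maturity and a response that alters maturation cannot be told apart by these measures. The developmental change may hold RNA of other cells. A biological difference between the stages remains a hypothesis.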

How the results depend on the processing

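The fits without the iOSN libraries of Ctrl 1 to 4, within the first submission set, and of cKO against WT within the later set, and the comparison of stress genes with Het mice, were chosen only after the result was seen. Of the values recomputed under alternatives set before the data were examined, 4739 kept their direction and side of the threshold or, for counts of called genes, stayed within 1.5 times. A further 383 fell short of the threshold or were counts lower by more than 1.5 times, 54 newly passed or were counts higher by that much, and 24 changed sign. Under those added later it was 72, 69, 0 and 2. For each change that follows the cause was not tested. With DESeq2 the counts were 2376 genes from precursor to immature neuron in place of 6 and 1178 in mature swap neurons in place of 783. They were 9 and 28 for the swap minus Ctrl differences in mature and immature neurons in place of 0. They were 408, 476 and 143 in Mor28 cKO, Het and WT in place of 199, 255 and 59, and 18 for their difference in place of 2 by edgeR. They were 67 between cKO and WT tdTomato neurons in place of 21, and 421 and 178 in Omp-Cre Het against WT and cKO against Het in place of 9 and 36. Without a filter on low counts 250 genes were called from precursor to immature neuron. With only the groups compared the counts were 0 from precursor to immature neuron, 3497 in Ctrl and 912 in swap immature neurons, 1 for the Mor28 difference and 4 for Omp-Cre Het against WT. With RLE size factors the split in immature swap neurons was 1190 higher and 1302 lower in place of 1576 and 1135, in Omp-Cre Het against WT 5 and 1 in place of 5 and 4 (also with library sizes without receptors), and from precursor to immature neuron 2 and 5 in place of 1 and 5. With the animal as a replicate block the counts were 3584 in Ctrl mature, 5278 for the stage difference, and 4885 and 1838 in swap immature and mature neurons. With this replicate block they were 634, 812 and 263 in Mor28 cKO, Het and WT, and 12 for their difference; for counts of called genes the block moved no other paired comparison by more than 1.5 times. Where samples share only a number, the replicate block gave 0 genes from precursor to immature neuron and 46 between Mor28 cKO and WT tdTomato neurons, and the samples did not all correlate best with their own number. With the submission set as a term the counts were 329, 445 and 123 in Mor28 cKO, Het and WT, 4 for their difference, 28 for Omp-Cre Het against WT and 67 for cKO against Het. Within the later set 3 genes were called in Het against WT and 24 in cKO against WT with 1 cKO library, assumed to vary like the others; within the first set 23 were called in cKO against Het. The later set alone could not give cKO against Het or cKO against WT with 2 or more libraries per group. Without the iOSN libraries of Ctrl 1 to 4 the counts were 551 in immature neurons and 775 for the stage difference.

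Leaving out each replicate in turn gave 0 to 5803 genes from precursor to immature neuron and 2174 to 2846 from immature to mature neuron. It gave 1335 to 1830 in Ctrl mature neurons, 631 to 2390 and 271 to 395 in swap immature and mature neurons. It gave 0 to 2 for the swap minus Ctrl difference in immature neurons, 90 to 147, 165 to 196 and 24 to 34 in Mor28 cKO, Het and WT, and 1 to 2 for their difference. It gave 13 to 24 between cKO and WT tdTomato neurons, and 681 to 1499, 26 to 106 and 4 to 216 in Omp-Cre cKO against WT, cKO against Het and Het against WT. Values that changed sign without passing any test were those of Olfr17 in immature swap neurons (-0.029 by DESeq2, -0.032 with RLE factors, -0.005 with only the groups compared, -0.194 with the replicate block, -0.46 to 0.56 leaving out replicates) and in Ctrl immature neurons (-0.018 with the replicate block, -0.019 with the set as a term, -2.08 without Ctrl 1 to 4, -0.27 to 0.56 leaving out replicates). Others were Ddit3 (-0.024 with the replicate block, -0.080 to 0.081 leaving out replicates) and Atf5 (0.038 without Ctrl 1 to 4) for the stage difference, Olfr151 (-0.042 to 1.83) and Olfr17 (-0.16 to 0.66) for the swap minus Ctrl difference in mature neurons leaving out replicates, and Ddit3 in Omp-Cre Het against WT (0.00 with the set as a term). With TPM in place of CPM the log2 ratio of group means was -0.32 for Olfr17 in Omp-Cre cKO against Het, -0.12 for Olfr151 from immature to mature neuron and 0.50 for Olfr1507 from precursor to immature neuron. With an estimated correlation 13 of 139 gene list tests held and 0 of 5 tests of the stress sets. With sets from immature neurons 3 passed, of which 1 kept its direction and 2 were reversed, those in Omp-Cre cKO against WT (adjusted p = 1.5e-05 and 1.9e-08, 0.23 and 0.27 with an estimated correlation), and in the Mor28 difference they reversed without passing (adjusted p = 0.43 for each).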

Other observations

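Tests of the floxed allele, the Cre response, strain DNA and maturity, and all comparisons of GFP neurons between genotypes, were chosen only after the result was seen. Kif5a, Dctn2, Pip4k2c and Dtx3, which lie next to Ddit3, were higher in libraries of mice with floxed Ddit3. A response of neurons with Cre to the loss of Ddit3 would appear between tdTomato and GFP neurons of the same cKO mice, where the highest change of the 4 genes was 0.12 on the log2 scale, far under the 0.89 to 1.23 between cKO and WT tdTomato neurons. In GFP neurons, which express the allele without Cre, the lowest change of the 4 genes between cKO and WT mice was 0.84, so the floxed allele or DNA linked to it may act on its neighbours apart from Cre. Both tests rest on GFP neurons that did not recombine Ddit3, which was not measured directly. DNA of another strain carried along with the allele remains open: in these GFP neurons the farthest gene called within 500 kb lay 95 kb away, as it did between cKO and WT tdTomato neurons (4 of 35 genes called). In Omp-Cre neurons it was 79.2 kb for cKO against Het (3 of 32 called) and 480 kb for cKO against WT (9 of 32 called), where set and genotype are largely confounded and 1423 of 14805 genes were called in all. The data cannot tell a short stretch of linked DNA from an effect of the inserted sequence. A test would be expression of these genes in floxed mice without Cre beside their strain of origin.

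More genes were called in Omp-Cre neurons between cKO and WT than between cKO and Het mice. All WT libraries belong to the later submission set. Between Het libraries of the first and the later set 66% of genes called in cKO against WT moved the same way, against 60.7% of all genes. That lies between the bounds set and decides nothing. In other cKO libraries against Het libraries of the first set the share was 84.8%, against 61.8 to 62.9% of all genes. Direction cannot explain a larger count or part loss of Ddit3 from its floxed allele.

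Receptor genes that lie next to each other may share their relation to reporter level: fold changes of 994 neighbouring pairs in Ctrl mature neurons were correlated (r = 0.395, permutation p = 1e-04, the smallest that 10000 permutations can give), as they were in 3614 pairs of receptors 2 to 5 places apart (r = 0.351). Reads shared only between adjacent genes would fade over such distances. The similarity of the receptors was not measured, and those 2 to 5 places apart may be similar too. Reads shared across a cluster therefore remain open as a cause. Genes in a cluster are not independent. A test would be reads that map to a single receptor.

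Other splits of the samples were fitted for each comparison of at least 3 samples per group. Among 40 splits for Ctrl mice only the real one reached 2104 genes in mature neurons (highest other 868, 0 if parting as many pairs). It alone reached 5391 in immature neurons (highest other 3069, exchanging 1 animal's labels). For the stage difference it alone reached 3289 (highest other 1, 0 if parting as many pairs). This share, 1 in 40, is the smallest possible, unadjusted and blind to animals, so chance stays open. Only 3 others part every pair, too few for a share under 0.05. For Mor28 neurons 1 of 35 splits reached 199 genes in cKO (highest other 1) and 1 of 50 reached 255 in Het (highest other 36), with 0 genes by edgeR in the 7 and 4 other splits that part every pair, likewise too few. Between animals 1 of 35 splits, the real one, reached 21 genes for cKO against WT tdTomato neurons (highest other 8). That is the smallest share that 35 splits can give, with no adjustment over the comparisons split. These splits do not hold the submission set apart either, since 3 of the 4 cKO libraries are of the first set. They therefore do not exclude chance or the set for this comparison. For the difference 1 of 35 splits reached 2 genes, but the highest other called 1, a margin too small to lean on. The 10 splits of 3 against 3 samples are too few for a share under 0.05; the real split gave 783 genes in mature swap neurons (highest other 1), 2711 in immature swap neurons (highest other 76) and 59 in Mor28 WT neurons (highest other 1). For the differences between swap and Ctrl mice, with 0 genes by edgeR (166 and 594 at an unadjusted p under 0.05 in mature and immature neurons, 9 and 28 by DESeq2), each of 40 splits reaches a count of 0, so the splits test nothing; the highest other split called 1 gene in mature and 90 in immature neurons. Among 100 splits of Omp-Cre libraries 1 split reached 1423 genes for cKO against WT (highest other 401), 2 splits reached 36 for cKO against Het (highest other 343) and 3 splits reached 9 for Het against WT (highest other 303). These splits do not hold the submission set apart, so they cannot exclude it for any of the 3, least of all for cKO against WT, where 4 of 5 cKO and 0 of 4 WT libraries are of the first set and 24 genes were called within the later set. For cKO against Het and Het against WT the highest split called several times the real count, which points to a structure of the samples. The split with 303 genes put every library of the first submission set into the same group, and within the later set the real comparison called 3 genes; within the first set cKO against Het called 23.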
